A study of Mus musculus with 42 samples.

How the data were processed

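Messenger RNA was measured on 42 one-colour Affymetrix arrays hybridised with biotin-labelled cRNA, 1 array per synovial fibroblast culture. Per the labels' protocols, the cells came from female BALB/c mice, wild-type or deficient in Tnfaip6 (the gene of TSG-6), in which arthritis had been induced with cartilage proteoglycan and an adjuvant. The cultures had been through up to 6 passages, were starved of serum overnight, and were then left untreated or treated for 12 h.

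The table as deposited holds log2 expression values for 45101 probe sets, made by RMA per the submitters' processing notes, with no version given in the sources used here. Each of the 45101 probe sets has a median within 1e-05 of 0 over the 42 arrays, so the deposited values are differences from that median and carry no absolute level. The base of the logarithm is not given in the sources used here. Base 2 was inferred from the largest range of a probe set, 9.81, which would be 14.15 doublings under a natural logarithm. Positive values were read as higher expression. The array medians lay between -0.0239 and 0.0252. The number of arrays per group limits the precision of every comparison.

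Of the probe sets, 34958 are listed with 1 gene, 932 with several and 9211 with none. Those with several genes or none were left out, and 34754 matched the table of gene names by gene number. Centred values give neither a highest mean nor a dim probe set. The planned filter therefore removed 0 probe sets. The planned choice of the brightest probe set per gene was replaced, after the values had been seen, by the probe set with the largest SD over the arrays. Probe sets that correlated above 0.7 with the 18S ribosomal RNA probe set (387) were avoided where a gene had another, and 67 genes had no other. This left 18194 genes, of which 9012 had more than 1 probe set. For the same reason the variance trend planned for limma was not used.

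All 42 arrays were fitted together in limma (lmFit and eBayes, with 30 residual and 4.23 prior degrees of freedom) with a mean for each of 12 groups, so that groups of 2 borrow their spread from the others. The 25 comparisons were each treatment against untreated cultures within a genotype (10), the genotypes within each condition (6), the difference between genotypes in each treatment response (5) and the combined against the single treatments (4). P-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. They measure only the spread between these cultures, since the labels call them biological replicates without saying that each came from a separate animal. A fold change is a difference of group means on the log2 scale, given ± SE.

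Before the data were examined, 28 gene lists were fixed, namely 16 of pathways, 11 of cell type markers and 1 of the neighbours of Tnfaip6 on chromosome 2. Each was tested with camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. The preset correlation called 246 of the 700 pairs of list and comparison, and 63 of these kept their call with an estimated correlation.

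The genes named in the text follow a rule fixed before the data were examined. For each treatment and for the untreated genotypes, these are the 10 largest rises and 10 largest falls among genes past the threshold whose arrays in 1 group all lay above those of the other. The other comparisons take the 3 largest each way, each list described takes the 4 members with the smallest adjusted p, and Tnfaip6 is reported in every comparison.

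Within each genotype the arrays fall into a pair of sets that the labels do not name. In the wild-type arrays, 33 of 44 probe sets with an empty gap of at least 1 log2 unit split the arrays in the same way, and in the knockout-labelled arrays 12 of 25 did. These culture sets hold 8 and 7 wild-type and 14 and 13 knockout-labelled arrays. They were found from the data, and the set was tried afterwards as a block, fixed within a genotype and random between genotypes. The knockout-labelled sets rest partly on the endothelial genes Cdh5 and Emcn. Replicate 1 of each treated wild-type group lies in set a and replicate 2 in set b, so their numbers go with the sets. The 18S probe set exceeded 1 on 15 arrays (5 wild-type, 10 knockout-labelled). Where a set holds 1 array of a group, that array is assumed to vary like the other groups.

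Correlations of fold changes between treatments share the untreated arrays, so 100 simulated draws without any effect, and arrays split between the comparisons, were set beside them. The limma fit was tested on simulated data with 66 or 67 genes changed at each of several sizes. Of the genes changed 2-fold it recovered 89.6% for TNFa in wild-type cultures, 94.0% for TNFa in knockout-labelled cultures and 77.6% for the difference between genotypes in the LPS response, each over 18194 genes. At 1.5-fold the shares were 41.8%, 89.6% and 20.9%, so small changes are missed more often in wild-type cultures and in the differences between genotypes.

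Alternatives fixed beforehand were cyclic loess normalization, a fit over only the groups compared, the replicate number as a block, the mean of a gene's probe sets, split untreated arrays and leaving out each array in turn. The culture-set block, leaving out the arrays with a high 18S signal and centring each array on its median were added after the data had been seen. The work used R 4.3.3, limma 3.58.1, the data.table package (1.17.8), Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Scanner files were not used here.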

Results

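Expression was profiled in cultures of synovial fibroblasts, the connective tissue cells of the joint lining, on 42 arrays, with 1 array per culture. The cells came from arthritic mice, wild-type (15 arrays) or deficient in Tnfaip6, the gene of the hyaluronan-binding protein TSG-6 (27 arrays). The wild-type arrays comprised 5 untreated cultures and 2 each with TNFa, LPS, TSG-6, hyaluronan (HA) or TSG-6 with HA. The knockout-labelled arrays comprised 8 untreated cultures, 3 with TSG-6 and 4 with each of the other treatments. Treatment lasted 12 h with TNFa at 5 ng/ml, LPS at 200 ng/ml, recombinant mouse TSG-6 at 120 ug/ml or HA at 24 ug/ml. The design compares treatments within a genotype and genotypes within a condition. Fold changes are on the log2 scale with their SE, p-values are adjusted limma values over 18194 genes, and each genotype holds a pair of culture sets that the labels do not name. Counts with the culture set as a block stand beside the main counts, and the number of arrays limits the precision of all of them.

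The probe set used for Tnfaip6 was not lower in the knockout-labelled arrays. Its mean centred value was -0.37 ± 0.16 (SD, n = 5) in untreated wild-type and -0.11 ± 0.23 (SD, n = 8) in untreated knockout-labelled cultures. The difference of 0.26 ± 0.15 did not pass the test (adjusted p = 0.22). Under TNFa the means were 0.23 ± 0.31 (SD, n = 2) and 0.34 ± 0.24 (SD, n = 4), and under LPS 0.24 ± 0.02 (SD, n = 2) and 0.26 ± 0.27 (SD, n = 4). Under TSG-6 they were -0.09 ± 0.05 (SD, n = 2) in wild-type and 0.27 ± 0.24 (SD, n = 3) in knockout-labelled cultures. HA gave -0.31 ± 0.12 (SD, n = 2) and 0.05 ± 0.36 (SD, n = 4), and TSG-6 with HA gave 0.02 ± 0.41 (SD, n = 2) and 0.18 ± 0.50 (SD, n = 4). Tnfaip6 passed the test in no comparison, and its smallest adjusted p was 0.0666 (TNFa in knockout-labelled cultures). Where the probe set lies relative to the disrupted part of the gene is not given in the sources used here, so its level does not check the labels, and the cultures are called knockout-labelled throughout.

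**Figure D1:**
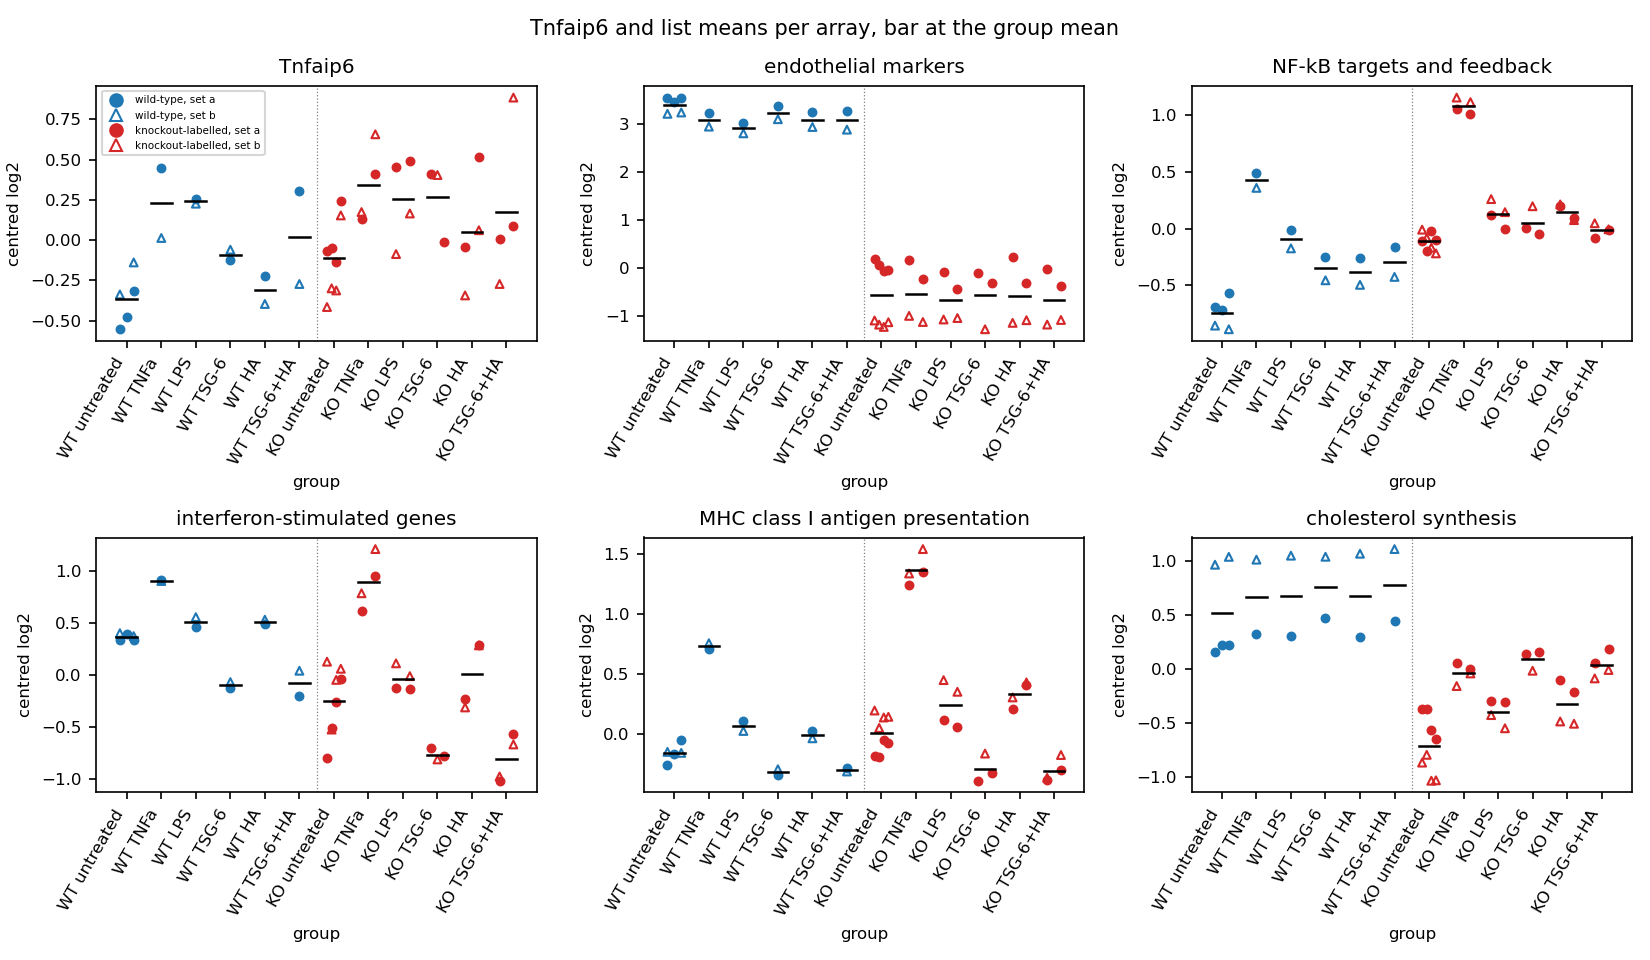
Centred log2 values of each array (points) in the 12 groups for Tnfaip6 and for the mean of 5 gene lists (endothelial, NF-kB, interferon, MHC class I, cholesterol synthesis), with bars at group means, wild-type in blue and knockout-labelled in red, filled circles for culture set a and open triangles for set b. In untreated cultures the Tnfaip6 means were -0.37 (wild-type) and -0.11 (knockout-labelled).

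TNFa is an inflammatory cytokine that activates the transcription factor NF-kB. In wild-type cultures (2 arrays against 5 untreated) the largest rises were in chemokines that attract T cells and neutrophils. Cxcl9 rose by 4.42 ± 0.47 (21.4-fold), Ccl20 by 4.10 ± 0.52, Cxcl11 by 3.92 ± 0.33, Ccl5 3.72 ± 0.63, Cxcl2 3.55 ± 0.18 and Cxcl10 3.51 ± 0.46. Acod1, the enzyme that makes itaconate, rose by 3.27 ± 0.37 and the matrix metalloproteinase Mmp10 by 3.07 ± 0.20. Cxcl3 and Cxcl16 completed the 10 largest rises. The largest falls were in Id4 (-2.48 ± 0.52), Id2 (-2.17 ± 0.28), Chrna7 (-2.31 ± 0.33), Cttnbp2 (-2.23 ± 0.28) and Npr3 (-2.14 ± 0.34). Next were Nmb, Ldb2, Mab21l2, Rerg and Lmcd1. The largest adjusted p among these 20 genes was 0.00319. Of 19 NF-kB targets and feedback genes, 17 rose (18 adjusted over the list alone), among them the inhibitors Nfkbia (1.35 ± 0.10) and Tnfaip3 (2.29 ± 0.18). Of 22 chemokines 11 rose (13 adjusted over the list alone), and of 14 genes of MHC class I antigen presentation 10 rose (12 adjusted over the list alone), including the immunoproteasome subunits Psmb10 (1.66 ± 0.15) and Psmb9 (1.54 ± 0.23). These 3 lists were called by camera with adjusted p = 3.28e-09, 7.62e-07 and 8.68e-06 with an estimated correlation. Cytokines and growth factors (7 of 23 rose and 1 fell, 8 adjusted over the list alone) and the enzymes and receptors of prostaglandins and nitric oxide (3 of 15 rose, 4 adjusted over the list alone) were called too. Camera called these lists with adjusted p = 0.00824 and 0.0239 with an estimated correlation. Of 27 interferon-stimulated genes 5 rose (5 adjusted over the list alone), such as Gbp2 (1.55 ± 0.21), and that list lost its call (adjusted p = 0.101 with an estimated correlation). In all, 466 genes changed (256 higher, 210 lower, 180 of them at least 2-fold), 835 with the culture set as a block. With each set tested alone (1 treated array in each set), 214 genes changed in both in the same direction. The count was 219 without WT TNFa replicate 2 and 230 without the arrays with a high 18S signal.

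In knockout-labelled cultures (4 arrays against 8) TNFa raised Ccl5 by 5.99 ± 0.46 (63.5-fold), Cxcl11 by 5.85 ± 0.24, Cxcl9 by 4.82 ± 0.34, Acod1 by 3.92 ± 0.27 and Nos2, the inducible nitric oxide synthase, by 3.81 ± 0.22. Spib (3.63 ± 0.19), Cxcl10 (3.60 ± 0.34), Slc2a6, the granulocyte growth factor Csf3 (3.52 ± 0.28) and the C-type lectin Clec4e completed the largest rises. The largest falls were in Plagl1 (-2.77 ± 0.36), Npr3 (-2.73 ± 0.24), the G-protein signalling regulator Rgs2 (-2.64 ± 0.16), Lrrn3 (-2.52 ± 0.24) and Hsd11b2, which inactivates glucocorticoids (-2.41 ± 0.28), then Pdk4, St8sia2, Sema3e, Thbs2 and Lmcd1. The 20 genes had adjusted p values up to 2.95e-06. Of the NF-kB genes 17 of 19 rose (18 adjusted over the list alone), of the chemokines 14 of 22 (14 adjusted over the list alone) and of the MHC class I genes 13 of 14 (13 adjusted over the list alone). These lists were called with adjusted p = 1.42e-06, 6.31e-05 and 1.6e-05 with an estimated correlation. Interferon-stimulated genes rose in 24 of 27 cases (25 adjusted over the list alone), among them Gbp3 (2.30 ± 0.20) and Parp14 (1.91 ± 0.17), and kept their call (adjusted p = 0.00358 with an estimated correlation). Smaller groups called were cytokines (12 of 23 rose and 1 fell, 14 adjusted over the list alone), prostaglandin and nitric oxide genes (5 of 15 rose and 1 fell, 7 adjusted over the list alone) and oxidative stress genes (9 of 14 rose and 2 fell, 11 adjusted over the list alone). The camera calls had adjusted p = 0.00749, 0.00109 and 0.0151 with an estimated correlation. Of 30 genes of hyaluronan synthesis, binding and breakdown 6 rose (9 adjusted over the list alone; adjusted p = 0.0258 with an estimated correlation), including the HA receptor Cd44 (1.53 ± 0.20), the innate receptor Tlr2 (1.58 ± 0.14) and the synthase Has1 (0.86 ± 0.15). Of 17 cholesterol synthesis genes 10 rose (14 adjusted over the list alone), such as Cyp51 (1.21 ± 0.25), and this list lost its call (adjusted p = 0.195 with an estimated correlation). The count was 2552 genes (1221 higher, 1331 lower, 429 at least 2-fold), 3463 with the culture set as a block. Each set tested alone gave 1083 genes changed in both in the same direction.

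The response to TNFa differed between the genotypes for 147 genes (102 higher and 45 lower in the knockout-labelled response, 404 with the culture set as a block). Treated wild-type groups hold 1 array per culture set, so the differences in response rest on about 2 culture sets per genotype. Genotype and cultures cannot be told apart in any of them, and the block takes out only the average difference between sets. Nos2 rose more in knockout-labelled cultures by 2.47 ± 0.38 (adjusted p = 0.000169), as did the adaptor gene Sntb1 (2.33 ± 0.24) and the transcriptional coactivator Cited1 (2.28 ± 0.21). Plagl1 (-2.69 ± 0.61), Mmp10 (-2.29 ± 0.25) and Hsd11b2 (-2.26 ± 0.48) had lower responses there. The MHC class I list was shifted upward (median 0.50, adjusted p = 0.0443 with an estimated correlation), with 2 of 14 genes past the threshold (5 adjusted over the list alone), Tapbpl (0.68 ± 0.15) and Psmb10 (0.76 ± 0.19). Leaving out WT TNFa replicate 2 reduced the count to 43, and leaving out the arrays with a high 18S signal to 32. Between the responses of the 2 genotypes the fold changes correlated across genes with r = 0.628, and 219 genes were higher in both, 133 lower in both and 3 opposite (17.18 and 15.36 for independent calls). Genes are not independent replicates.

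LPS is a cell wall component of bacteria that acts through a Toll-like receptor. In wild-type cultures (2 arrays against 5) it raised Cxcl2, a neutrophil attractant, by 4.31 ± 0.18 (19.9-fold) and the growth factors of granulocytes and macrophages, Csf2 and Csf3, by 4.29 ± 0.26 and 4.20 ± 0.38. Ccl5 rose by 3.54 ± 0.63, Cxcl3 by 3.42 ± 0.21, platelet factor Pf4 by 2.96 ± 0.16, Stfa3 by 2.88 ± 0.33, the iron-siderophore binder Lcn2 by 2.79 ± 0.43, Ccl20 by 2.79 ± 0.52 and the arginase Arg2 by 2.70 ± 0.33. The largest fall was in the endothelial tight junction gene Cldn5 (-2.40 ± 0.25), followed by Scn3a (-1.96 ± 0.37), Chrna7, Npr3, the fatty acid binding protein Fabp4 (-1.72 ± 0.33), Nmb, Eya4, Cldn1, Fabp5 and Ldb2. Among these 20 genes the largest adjusted p was 0.0325. Of the chemokines 12 of 22 rose (13 adjusted over the list alone), of the NF-kB genes 9 of 19 (12 adjusted over the list alone) and of the cytokines 6 of 23 (6 adjusted over the list alone). For these lists camera gave adjusted p = 4.16e-07, 8.18e-07 and 0.00153 with an estimated correlation. Of 19 hypoxia and glycolysis genes 5 rose (9 adjusted over the list alone; adjusted p = 5.8e-05 with an estimated correlation), such as the hexokinase Hk2 (0.87 ± 0.16) and Bnip3 (1.01 ± 0.15). Of 13 endothelial markers, Cldn5 alone fell (4 adjusted over the list alone), with a list median of -0.48 whose call was lost (adjusted p = 0.15 with an estimated correlation). In all, 217 genes changed (134 higher, 83 lower, 97 at least 2-fold), 523 with the culture set as a block. In both sets, each tested alone (with 1 treated array in each), 113 genes changed in the same direction. The count was 93 without WT LPS replicate 1, 109 without replicate 2 and 118 without the arrays with a high 18S signal.

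In knockout-labelled cultures (4 against 8) LPS raised Ccl5 by 4.31 ± 0.46 (19.8-fold), Nos2 by 2.42 ± 0.22, U90926 by 1.95 ± 0.31 and Mmp9 by 1.77 ± 0.19. Cxcl9, Cxcl11, Fabp7, Clec4e, Lgi2 and Serpinb1b followed. Falls were led by Hsd11b2 (-1.86 ± 0.28), St8sia2 (-1.60 ± 0.21) and Ldb2 (-1.46 ± 0.27). They included the immediate early transcription factors Egr3 (-1.37 ± 0.22), Egr1 (-1.28 ± 0.17) and Egr2 (-1.18 ± 0.16), besides Lrrc17, Inmt, Cybrd1 and Slc5a3. The largest adjusted p of the 20 was 0.00567. Of the chemokines 11 of 22 rose (14 adjusted over the list alone), of the cytokines 8 of 23 (12 adjusted over the list alone), including Il6 (2.09 ± 0.37), and of the NF-kB genes 5 of 19 (7 adjusted over the list alone). The list tests gave adjusted p = 0.000135, 0.0133 and 0.0115 with an estimated correlation. Hypoxia and glycolysis genes rose in 4 of 19 cases (8 adjusted over the list alone) and hyaluronan genes in 2 of 30 (Cd14 and Has1; 4 adjusted over the list alone). Camera calls for these had adjusted p = 0.00465 and 0.00677 with an estimated correlation. In all, 326 genes changed (177 higher, 149 lower, 63 at least 2-fold), 720 with the culture set as a block. When the sets were tested separately, 81 genes were higher and 120 lower in set a, 177 higher and 99 lower in set b, and 114 changed in both in the same direction. Without KO LPS replicate 1 the count was 200, without replicate 3 it was 213, and without the arrays with a high 18S signal 134.

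The responses to LPS differed between the genotypes for 39 genes (12 higher, 27 lower in the knockout-labelled response; 103 with the culture set as a block; 8 higher and 35 lower with cyclic loess). The responses of Csf2 (-3.19 ± 0.32, adjusted p = 4.33e-08), Cxcl2 (-3.00 ± 0.23, adjusted p = 1.14e-10) and Csf3 (-2.75 ± 0.47) were lower in knockout-labelled cultures. Cldn5 (2.27 ± 0.31), Fabp4 (2.04 ± 0.41) and Nmb (1.56 ± 0.24) fell in wild-type cultures and had higher responses in knockout-labelled ones. Of the NF-kB genes 4 of 19 had a smaller response (6 adjusted over the list alone) and of the chemokines 4 of 22 (7 adjusted over the list alone). They were called by camera with adjusted p = 0.000369 and 0.00672 with an estimated correlation. In untreated cultures Cxcl2 was already higher in the knockout-labelled group by 2.83 ± 0.13. Cldn5 and Fabp4 were already lower there, with mean centred values of -0.205 and -0.387 against 3.482 and 1.641 in wild-type. Under LPS the knockout-labelled mean of Cldn5 was -0.334. The count was 23 without WT LPS replicate 2 and 20 without the arrays with a high 18S signal. Between genotypes the LPS fold changes correlated across genes with r = 0.543 (0.382 without WT LPS replicate 1), and 62 genes were higher in both, 14 lower in both and 1 opposite (1.3 and 0.68 for independent calls).

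**Figure D2:**
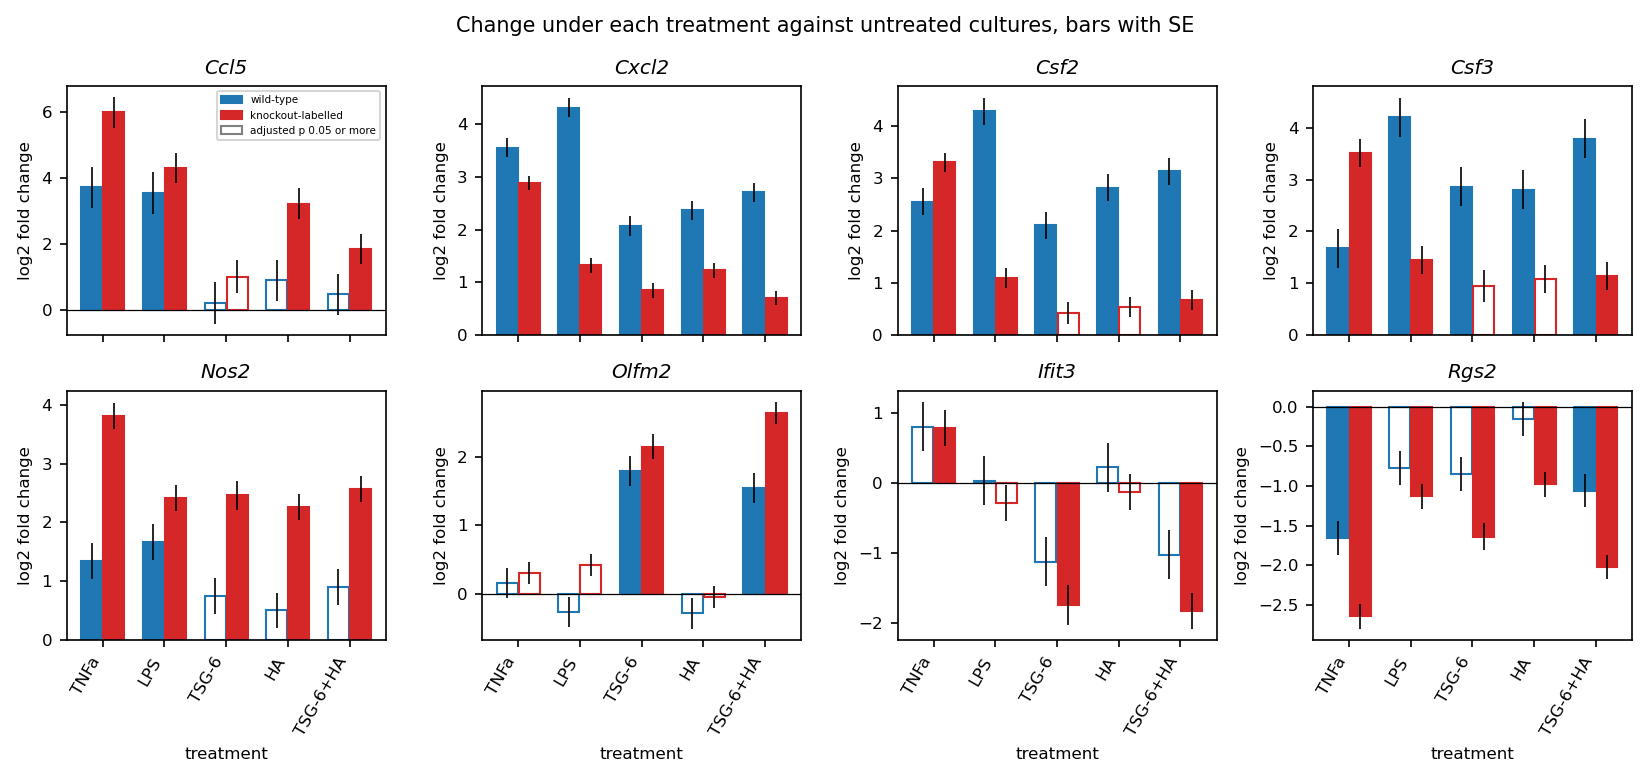
Bars give the log2 fold change (error bars, moderated SE) against untreated cultures of the same genotype for Ccl5, Cxcl2, Csf2, Csf3, Nos2, Olfm2, Ifit3 and Rgs2 under each treatment, with wild-type in blue and knockout-labelled in red, filled where the adjusted p was under 0.05 and open elsewhere. Under LPS the bars for Csf2 reach 4.29 (wild-type) and 1.09 (knockout-labelled).

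Recombinant TSG-6 raised Serpinb2 by 3.06 ± 0.50 (8.37-fold) in wild-type cultures (2 against 5), Csf3 by 2.86 ± 0.38, Csf2 by 2.10 ± 0.26 and Olfm2 by 1.80 ± 0.22. Cxcl2, Mmp10, Cxcl3, Cxcl16, Fbp1 and Nt5e followed. The largest falls were in Cdo1 (-1.65 ± 0.25), Npr3 (-1.60 ± 0.34), Rspo2 (-1.53 ± 0.33), Cldn1 (-1.52 ± 0.30) and Sned1 (-1.50 ± 0.32), ahead of Id2, Nmb, Ramp3, Ntm and Fgf18. No adjusted p of the 20 exceeded 0.047. Of the NF-kB genes 4 of 19 rose (10 adjusted over the list alone), of the chemokines 5 of 22 (8 adjusted over the list alone) and of the hypoxia and glycolysis genes 1 of 19 (Hk2, 1.03 ± 0.16; 6 adjusted over the list alone). The tests of these lists gave adjusted p = 0.000161, 0.00026 and 0.000984 with an estimated correlation. Of 27 interferon-stimulated genes 1 fell, the antiviral synthetase Oas3 (-0.67 ± 0.16; 2 adjusted over the list alone), and the list kept its call (median -0.41, adjusted p = 0.0446 with an estimated correlation). In all, 78 genes changed (50 higher, 28 lower, 36 at least 2-fold), 214 with the culture set as a block. Separate tests of the sets (1 treated array in each set) shared 40 genes changed in the same direction. The count was 20 without WT TSG6 replicate 1 and 38 without replicate 2, and 34 in a fit over only the groups compared.

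In knockout-labelled cultures (3 against 8) TSG-6 raised Nos2 by 2.46 ± 0.25 (5.52-fold), Tfpi2 by 2.41 ± 0.45, Fabp7 by 2.27 ± 0.30, Olfm2 by 2.15 ± 0.18, Col8a2 by 1.86 ± 0.19, and Mmp9 by 1.85 ± 0.21. Tgfbi rose by 1.80 ± 0.34, and U90926, Ccl20 and Fkbp11 were next. Falls were led by Sned1 (-1.81 ± 0.26), Plin4 (-1.78 ± 0.20), the interferon-stimulated Ifit3 (-1.74 ± 0.28) and Ntn4 (-1.71 ± 0.19), then Cyp26b1, Hsd11b2, Rgs2, Selenbp1, Gem and Adh1. The 20 genes had adjusted p values up to 0.02. Hyaluronan genes rose in 3 of 30 cases (5 adjusted over the list alone), namely the HA-binding proteoglycan Vcan (1.52 ± 0.19), the link protein Hapln1 (1.46 ± 0.33) and the synthase Has2 (0.98 ± 0.24). The list kept its call (adjusted p = 0.028 with an estimated correlation). Cholesterol synthesis genes rose in 10 of 17 cases (15 adjusted over the list alone; median 0.77) and myofibroblast and TGF-beta genes in 7 of 20 with 1 fall (12 adjusted over the list alone), including the contractile light chain Myl9 (1.40 ± 0.32). Both lists lost their call (adjusted p = 0.0885 with an estimated correlation for each). The control probe sets of Actb also moved, with 5' minus 3' values of 0.009 to 0.128 under TSG-6 and 0.048 to 0.138 under TSG-6 with HA against -0.735 to -0.009 in untreated cultures. Those of Gapdh overlapped (-0.108 to 0.078 and -0.077 to 0.074 against -0.231 to 0.132). Interferon-stimulated genes fell in 5 of 27 cases (11 adjusted over the list alone; median -0.45; adjusted p = 0.12 with an estimated correlation), with Ifit2 at -1.31 ± 0.29. MHC class I genes fell in 3 of 14 (5 adjusted over the list alone; adjusted p = 0.0944 with an estimated correlation). Of 28 collagens and structural matrix genes 5 rose and 1 fell (7 adjusted over the list alone; adjusted p = 0.468 with an estimated correlation), including Col3a1 (1.17 ± 0.22) and Col5a2 (0.94 ± 0.14). In all, 864 genes changed (382 higher, 482 lower, 106 at least 2-fold), 1539 with the culture set as a block. The sets tested alone differed in the balance of directions, with 310 higher and 691 lower in set a and 209 higher and 87 lower in set b, which holds 1 treated array, and 171 changed in both in the same direction. The count was 322 without KO TSG6 replicate 1, 465 without replicate 2, 435 without the arrays with a high 18S signal and 560 in a fit over only the groups compared.

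Responses to TSG-6 differed between genotypes for 15 genes (5 higher, 10 lower; 87 with the culture set as a block; 2 higher and 7 lower with cyclic loess). Col8a2 (1.48 ± 0.30), Sstr2 (1.13 ± 0.17) and Nectin2 (0.93 ± 0.19) had higher responses in knockout-labelled cultures, and Fbp1 (-1.72 ± 0.32), Csf2 (-1.67 ± 0.33) and Sema7a (-1.34 ± 0.21) lower ones. The count moved with single arrays, to 7 without WT untreated replicate 4, 1 without WT TSG6 replicate 1, 4 without WT TSG6 replicate 2, and 5, 8 and 9 without KO TSG6 replicates 1, 2 and 3. The fold changes of the genotypes correlated across genes with r = 0.465, and 24 genes were higher in both, 13 lower in both and 1 opposite (1.05 and 0.74 for independent calls).

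HA raised Csf2 by 2.82 ± 0.26 (7.08-fold), Csf3 by 2.81 ± 0.38 and Cxcl2 by 2.37 ± 0.18 in wild-type cultures (2 against 5). These were followed by Cxcl3, Arg2, Lcp2 (1.54 ± 0.23), Pf4 (1.53 ± 0.16), Cxcl16, Cxcl1 and Kcnq5. It lowered 7 genes, Cldn5 (-1.24 ± 0.25), Clec1a (-1.01 ± 0.19), Sprr1a, Tm6sf1, Sstr2 (-0.90 ± 0.13), Camk4 and Gprc5b. The adjusted p of these genes reached 0.0379. Of the NF-kB genes 3 of 19 rose (7 adjusted over the list alone) and of the chemokines 3 of 22 (7 adjusted over the list alone). The list tests gave adjusted p = 0.000678 with an estimated correlation for each. In all, 24 genes changed (17 higher, 7 lower, 13 at least 2-fold; 25 higher and 2 lower with cyclic loess), 68 with the culture set as a block. Tested alone, the sets (1 treated array in each) shared 15 genes changed in the same direction. A fit over only the groups compared gave 11.

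In knockout-labelled cultures (4 against 8) HA raised Ccl5 by 3.22 ± 0.46 (9.33-fold), Nos2 by 2.26 ± 0.22, Ccl3 by 1.43 ± 0.35, Mmp9 by 1.33 ± 0.19, the LPS-binding protein Lbp by 1.28 ± 0.28 and Cxcl2 by 1.22 ± 0.14. Col5a3, Cyp7b1, Vnn3 and Serpinb1b followed. Ldb2 (-1.15 ± 0.27), Egr3 (-1.09 ± 0.22) and Egr1 (-1.05 ± 0.17) fell most, followed by Cybrd1, Pcdh9, Rgs2, Slc9a3r2, Slc5a3, Chdh and Kcnma1. The adjusted p of these genes reached 0.0483. Chemokines rose in 7 of 22 cases (13 adjusted over the list alone), NF-kB genes in 4 of 19 (9 adjusted over the list alone) and MHC class I genes in 3 of 14 (7 adjusted over the list alone). Camera called these lists with adjusted p = 0.000164, 0.00314 and 0.00556 with an estimated correlation. In all, 117 genes changed (78 higher, 39 lower, 18 at least 2-fold), 305 with the culture set as a block. For the sets tested alone, 41 genes changed in both in the same direction. The count was 61, 77 and 67 without KO HA replicates 1, 2 and 3, 63 without the arrays with a high 18S signal and 60 in a fit over only the groups compared.

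The difference between genotypes in the HA response passed for 8 genes (3 higher, 5 lower; 18 with the culture set as a block; 0 higher and 4 lower with cyclic loess; 3 and 3 with each array centred on its median). Sprr1a (1.09 ± 0.22), Sstr2 (0.99 ± 0.17) and Gprc5b (0.78 ± 0.14), which fell in wild-type cultures, had higher responses in knockout-labelled ones, and Csf2 (-2.29 ± 0.32), Lcp2 (-1.46 ± 0.29) and Pf4 (-1.39 ± 0.20) lower ones. The count was 4 without WT untreated replicate 4 or 5, and 2 without WT HA replicate 1 or 2. It was 5, 4, 5 and 5 without KO untreated replicates 2, 5, 6 and 8, 3 without KO HA replicate 1 or 3, and 1 without the arrays with a high 18S signal. The HA fold changes of the genotypes correlated across genes with r = 0.437, and 9 genes were higher in both (0.07 for independent calls).

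TSG-6 together with HA raised Csf3 by 3.79 ± 0.38 (13.8-fold), Csf2 by 3.13 ± 0.26, Cxcl2 by 2.71 ± 0.18 and Serpinb2 by 2.62 ± 0.50 in wild-type cultures (2 against 5), followed by Cxcl3, Ccl20, Lcn2, Arg2, Fbp1 and Cxcl16. Cldn1 (-2.04 ± 0.30), Ramp3 (-1.74 ± 0.29), Cdo1 (-1.68 ± 0.25), Id2 and Cldn5 (-1.64 ± 0.25) fell most, then Nmb, Scn3a, Sned1, Tm6sf1 and Rspo2. Among these 20 genes the largest adjusted p was 0.0455. NF-kB genes rose in 7 of 19 cases (11 adjusted over the list alone), chemokines in 6 of 22 (8 adjusted over the list alone) and hypoxia and glycolysis genes in 2 of 19 (5 adjusted over the list alone). These lists were called with adjusted p = 0.000721, 0.000721 and 0.0127 with an estimated correlation. In all, 146 genes changed (67 higher, 79 lower, 56 at least 2-fold; 85 higher and 55 lower with cyclic loess), 448 with the culture set as a block. Separately tested sets (1 treated array in each) shared 68 genes changed in the same direction. The count was 395 without WT TSG6HA replicate 1, 59 without replicate 2, 51 without the arrays with a high 18S signal and 49 in a fit over only the groups compared.

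In knockout-labelled cultures (4 against 8) the combination raised Olfm2 by 2.64 ± 0.16 (6.22-fold), Nos2 by 2.56 ± 0.22, Tfpi2 by 2.48 ± 0.41, Fabp7 by 2.21 ± 0.27, Mmp9 by 2.06 ± 0.19, S100a8 by 1.94 ± 0.40 and Il6 by 1.83 ± 0.37. U90926, Tgfbi and Fkbp11 were next. Rgs2 (-2.02 ± 0.16), Ntn4 (-1.95 ± 0.17), Plin4 (-1.95 ± 0.18), Akr1c14 and Sned1 fell most, then Ifit3 (-1.82 ± 0.25), Selenbp1, Hsd11b2, Chdh and Gem. No adjusted p of the 20 exceeded 0.00199. Hyaluronan genes rose in 5 of 30 cases (7 adjusted over the list alone; adjusted p = 0.0178 with an estimated correlation), among them Vcan (1.57 ± 0.17), Has2 (0.90 ± 0.22) and Cd44 (0.62 ± 0.20). Cholesterol synthesis genes rose in 12 of 17 cases (16 adjusted over the list alone) and myofibroblast genes in 8 of 20 with 1 fall (11 adjusted over the list alone). Interferon-stimulated genes fell in 9 of 27 (17 adjusted over the list alone) and MHC class I genes in 5 of 14 (8 adjusted over the list alone). All 4 lists lost their call (adjusted p = 0.136 with an estimated correlation for each). Collagens rose in 6 of 28 cases and fell in 1 (9 adjusted over the list alone), with a list median of -0.01, a mean of 0.19 and an upward test that was lost (adjusted p = 0.371 with an estimated correlation). In all, 1809 genes changed (606 higher, 1203 lower, 156 at least 2-fold), 2648 with the culture set as a block, 1111 without KO TSG6HA replicate 1 and 1080 without the arrays with a high 18S signal. Between the sets, each tested alone, 600 genes changed in the same direction in both.

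The responses to TSG-6 with HA differed between genotypes for 33 genes (7 higher, 26 lower; 211 with the culture set as a block; 12 higher and 25 lower with each array centred on its median). Cldn5 (1.51 ± 0.31), Tm6sf1 (1.34 ± 0.17) and Sstr2 (1.23 ± 0.17) had higher responses in knockout-labelled cultures, and Csf3 (-2.65 ± 0.47), Csf2 (-2.46 ± 0.32) and Plin4 (-2.09 ± 0.30) lower ones. Cldn5 and Tm6sf1 fell in wild-type cultures (Cldn5 from 3.482 to 1.846, against -0.205 to -0.33 in knockout-labelled ones). Of 19 NF-kB genes 3 had a lower response (6 adjusted over the list alone; median -0.41, adjusted p = 0.0326 with an estimated correlation). The count was 59 without WT TSG6HA replicate 1, 20 without replicate 2, 20 without KO TSG6HA replicate 3 and 7 without the arrays with a high 18S signal. Fold changes of the genotypes correlated across genes with r = 0.487, and 40 genes were higher in both and 46 lower in both (2.23 and 5.22 for independent calls).

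Set against HA alone, the combination in knockout-labelled cultures (4 against 4) raised Olfm2 by 2.68 ± 0.19, Tfpi2 by 2.49 ± 0.47 and Tgfbi by 2.06 ± 0.35. It lowered Ifit3 (-1.69 ± 0.29), Sned1 (-1.58 ± 0.27) and Ifitm1 (-1.58 ± 0.22). Interferon-stimulated genes fell in 15 of 27 cases (25 adjusted over the list alone; median -0.78) and MHC class I genes in 10 of 14 (12 adjusted over the list alone; median -0.56), with Psmb9 at -1.42 ± 0.20 and Psmb8 at -1.19 ± 0.20. Both lists kept their call (adjusted p = 0.00536 and 0.000202 with an estimated correlation). The 5' minus 3' values of the Actb control were 0.048 to 0.138 in the combination and -0.13 to -0.05 under HA, and those of Gapdh overlapped (-0.077 to 0.074 and -0.065 to 0.075). Myofibroblast and TGF-beta genes rose in 4 of 20 cases and fell in 1 (8 adjusted over the list alone; adjusted p = 0.0266 with an estimated correlation). In all, 325 genes changed (115 higher, 210 lower; 820 with the culture set as a block), 169 without KO TSG6HA replicate 1 and 179 without replicate 3, and 51 in a fit over only the groups compared. The balance of directions turned between the sets tested alone (2 against 2 arrays each), with 56 higher and 194 lower in set a, 108 higher and 61 lower in set b, and 76 genes changed in both in the same direction. The 18S signal differed too. In set a it was high on KO TSG6HA replicate 2 (4.114) and on no HA array. In set b it was high on KO TSG6HA replicate 4 (1.484) and KO HA replicate 4 (4.126). The set and the 18S signal cannot be told apart here. Against TSG-6 alone, limma called 0 genes in the combination in knockout-labelled cultures, with 612 at an unadjusted p under 0.05. In wild-type cultures (2 against 2) the combination differed from HA alone in 1 gene, Olfm2 (1.83 ± 0.26, adjusted p = 0.000918), with 580 at an unadjusted p under 0.05. The limma count was 19 with the culture set and 8 with the replicate number as a block, 0 without WT HA replicate 1 or WT TSG6HA replicate 2 and 23 without WT TSG6HA replicate 1. From TSG-6 alone it differed in 0 genes by limma, with 456 at an unadjusted p under 0.05 and 26 genes without WT TSG6HA replicate 1. In the wild-type comparison with HA the interferon-stimulated genes had a median of -0.57, and their call was lost (adjusted p = 0.113 with an estimated correlation).

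Treatments of the same genotype share their untreated arrays, which alone gives correlated fold changes. Treated arrays of the same number also deviated together (median r of 0.565 in wild-type cultures, where the number goes with the culture set, and 0.468 in knockout-labelled ones). Neither the split nor the simulated values below take this out. In wild-type cultures the fold changes of TNFa and LPS correlated across genes with r = 0.625 (0.422 with the untreated arrays split, 0.286 in simulated data without an effect). The value was 0.672 for TSG-6 and the combination (0.382 split, 0.283 simulated) and 0.606 for HA and the combination (0.346 split, 0.286 simulated). TSG-6 and LPS gave 0.624 (0.342 split) and HA and LPS 0.62 (0.358 split). In knockout-labelled cultures the values were 0.686 for TNFa and LPS (0.514 split, 0.333 simulated), 0.83 for TSG-6 and the combination (0.646 split, 0.303 simulated) and 0.582 for HA and the combination (0.349 split). They were 0.551 for TSG-6 and LPS (0.345 split) and 0.781 for HA and LPS (0.45 split, 0.336 simulated). Among knockout-labelled responses, 68 genes were higher and 36 lower under both HA and LPS and 0 opposite by limma. With the untreated arrays split the means were 28 and 15, and independent calls, which leave out the shared arrays, would give 0.76 and 0.32. TSG-6 and LPS shared 80 higher and 108 lower genes, with 2 opposite (43.5 and 48.9 split, 3.72 and 3.95 for independent calls). The covariance of the fold changes was 0.0265 for HA and LPS (0.00845 simulated) and 0.0281 for TSG-6 and LPS (0.00839 simulated). The pair of HA and LPS was added after the fold changes had been seen.

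Untreated knockout-labelled cultures differed widely from untreated wild-type cultures (8 arrays against 5). The cartilage matrix genes Cnmd (6.24 ± 0.38, 75.4-fold), Comp (4.42 ± 0.36) and Thbs4 (4.36 ± 0.62), the joint lubricant gene Prg4 (4.41 ± 0.18) and the prostaglandin-degrading enzyme gene Hpgd (5.62 ± 0.51) were higher in the knockout-labelled group. So were the BMP antagonist Chrdl1 (4.95 ± 0.34), Egfl6, Mme, Steap4 and Angptl7. Prom1 (-7.77 ± 0.30, 218-fold), Serpinb6b (-7.65 ± 0.16), the lymphatic vessel HA receptor Lyve1 (-7.23 ± 0.20), the endothelin receptor Ednrb (-7.18 ± 0.26) and Car8 (-6.83 ± 0.18) were lower. So were Ctla2b (-6.68 ± 1.21), the endothelial sialomucin Emcn (-6.56 ± 1.17), the vascular phosphatase Ptprb, Hoxd10 and Klhl4. The largest adjusted p of these 20 genes was 2.23e-05. Hpgd, Thbs4, Egfl6 and Mme are also among the genes that separate the wild-type culture sets, and Ctla2b and Emcn among those that separate the knockout-labelled ones. Of 13 endothelial markers, none of which another list holds, 12 were lower (12 adjusted over the list alone) (list median -4.67). Examples are the receptor tyrosine kinase Tie1 (-5.42 ± 0.21), Egfl7 (-5.21 ± 0.25), the guidance receptor Robo4 (-4.67 ± 0.16) and Cldn5 (-3.69 ± 0.17). The list had adjusted p = 1.92e-16 by camera and 0.0624 with an estimated correlation. The count was 6832 genes (3872 higher, 2960 lower, 1719 at least 2-fold), 5992 with the culture set as a random block. The comparison rests on about 2 culture sets per genotype, so the genotype and the cultures cannot be told apart.

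**Figure D3:**
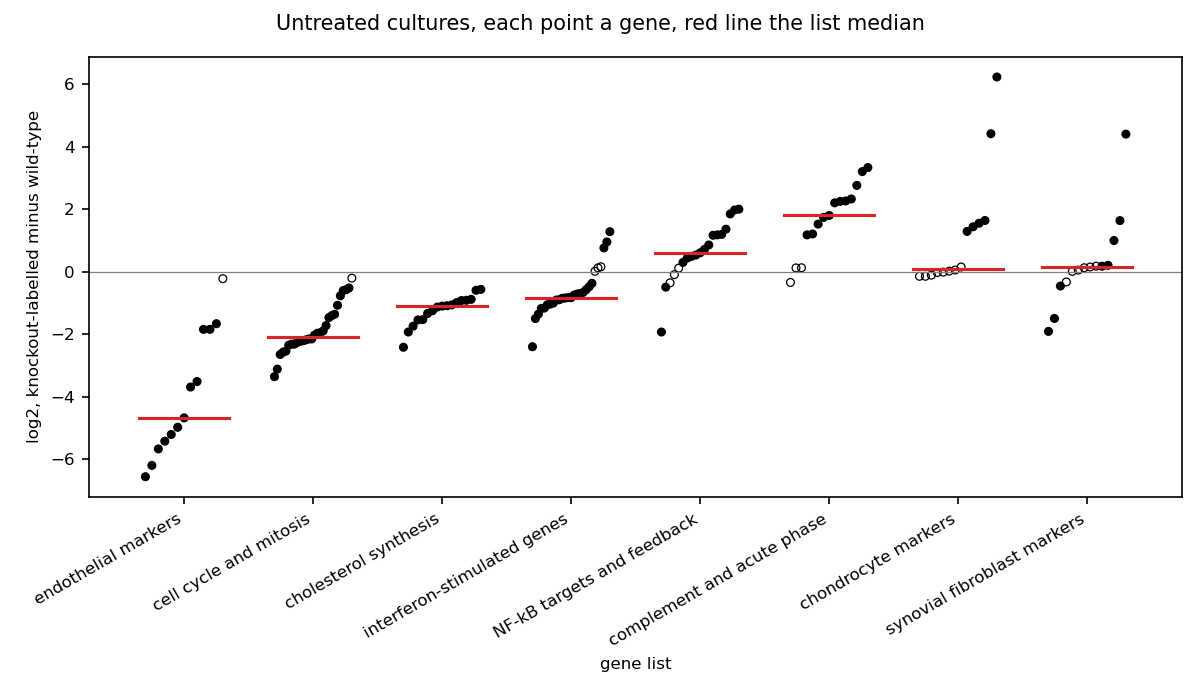
Each point is the log2 fold change of a gene, untreated knockout-labelled (n = 8) minus untreated wild-type (n = 5), for the measured members of 8 gene lists, filled where the adjusted p was under 0.05, and the red lines are list medians. The endothelial median lies at -4.67 and the cell cycle median at -2.09.

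Genes of cell cycle and mitosis were lower in knockout-labelled untreated cultures in 27 of 28 cases (27 adjusted over the list alone; median -2.09), including the proliferation marker Mki67 (-3.35 ± 0.27) and the mitotic motor Kif11 (-2.21 ± 0.13), with adjusted p = 0.102 with an estimated correlation. All 17 cholesterol synthesis genes were lower (17 adjusted over the list alone, median -1.10, adjusted p = 0.262 by camera with an estimated correlation), among them the synthase Hmgcs1 (-1.53 ± 0.16). The list mean also went with the culture set, at 0.158 to 0.222 (set a) and 0.965 to 1.038 (set b) in untreated wild-type arrays. In untreated knockout-labelled arrays it was -0.646 to -0.371 (set a) and -1.036 to -0.796 (set b). Complement and acute phase genes were higher in 12 of 15 cases (12 adjusted over the list alone, median 1.80, adjusted p = 0.299 by camera with an estimated correlation), such as Lcn2 (3.34 ± 0.30) and C1ra (2.27 ± 0.26). Their mean was -1.385 to -1.212 in set a and -2.427 to -2.387 in set b of the untreated wild-type arrays. It overlapped between the untreated knockout-labelled sets (-0.189 to 0.033 and -0.175 to 0.188). NF-kB genes were higher in 14 of 19 and lower in 2 (17 adjusted over the list alone; adjusted p = 0.123 with an estimated correlation). Chemokines were higher in 8 of 22 and lower in 2 (10 adjusted over the list alone; adjusted p = 0.37 with an estimated correlation). Interferon-stimulated genes were lower in 21 of 27 and higher in 3 (24 adjusted over the list alone; adjusted p = 0.299 with an estimated correlation), with Oasl1 at -2.40 ± 0.17. Matrix proteases and inhibitors were higher in 18 of 27 and lower in 3 (24 adjusted over the list alone; adjusted p = 0.299 with an estimated correlation), with Serpinb2 at 4.00 ± 0.34 and the urokinase Plau at -3.61 ± 0.28. Of 20 endoplasmic reticulum stress genes 10 were lower and 1 higher (11 adjusted over the list alone), and of 20 myofibroblast genes 8 were lower and 2 higher (10 adjusted over the list alone). Both calls were lost (adjusted p = 0.299 and 0.37 with an estimated correlation). Chondrocyte markers were higher in 6 of 14 cases (6 adjusted over the list alone), including the cartilage regulator Sox9 (1.55 ± 0.15), with adjusted p = 0.103 with an estimated correlation.

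The other 17 lists were not called in untreated cultures. Cytokines were higher in 10 of 23 and lower in 2 (12 adjusted over the list alone). MHC class I genes were higher in 6 of 14 and lower in 1 (7 adjusted over the list alone), and prostaglandin and nitric oxide genes higher in 7 of 15 and lower in 3 (10 adjusted over the list alone). Hyaluronan genes were higher in 7 of 30 and lower in 9 (17 adjusted over the list alone), with the scavenger receptor Stab1 at -6.18. Collagens were higher in 8 of 28 and lower in 13 (21 adjusted over the list alone), with a median of -0.21 against a mean of 0.01. Oxidative stress genes were higher in 4 of 14 and lower in 3 (7 adjusted over the list alone), hypoxia and glycolysis genes higher in 7 of 19 and lower in 3 (10 adjusted over the list alone). The 47 chromosomal neighbours of Tnfaip6 were higher in 13 and lower in 6 (19 adjusted over the list alone). Synovial fibroblast markers were higher in 5 of 14 and lower in 3 (8 adjusted over the list alone), with Thy1 at -1.91. Of 20 macrophage markers 1 was higher and 3 lower (4 adjusted over the list alone), with a median of 0.09 against a mean of -0.12. Of 8 adipocyte markers 2 were higher and 1 lower (4 adjusted over the list alone; median 0.02), of 10 pericyte markers 1 lower (1 adjusted over the list alone; median 0.05) and of 10 epithelial markers 2 lower (2 adjusted over the list alone; median 0.02), each with a downward test direction. Osteoblast markers were higher in 2 of 6 (2 adjusted over the list alone) and skeletal muscle markers higher in 2 of 12 and lower in 1 (3 adjusted over the list alone). Of 12 lymphocyte and 3 erythroid markers, 0 passed by limma (0 adjusted over the list alone in each), and 1 and 0 had an unadjusted p under 0.05.

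Under each treatment Cnmd, Hpgd, Serpinb6b and Prom1 were again among the 3 largest differences each way between the genotypes. Cnmd was higher in knockout-labelled cultures by 5.59 ± 0.58 under TNFa, 5.80 ± 0.58 under LPS, 5.63 ± 0.61 under TSG-6, 5.64 ± 0.58 under HA and 5.55 ± 0.58 under TSG-6 with HA. In the same order, Hpgd was higher by 5.35 ± 0.77, 6.33 ± 0.77, 5.78 ± 0.81, 5.61 ± 0.77 and 5.33 ± 0.77. The third largest rise was Egfl6, except under TSG-6, where it was the endopeptidase Mme (4.99 ± 0.71). In that order Serpinb6b was lower, at -7.56 ± 0.24, -7.35 ± 0.24, -7.10 ± 0.26, -7.29 ± 0.24 and -7.04 ± 0.24, and Prom1 at -7.22 ± 0.45, -7.16 ± 0.45, -7.34 ± 0.48, -7.37 ± 0.45 and -7.29 ± 0.45. The third was Car8 under TNFa and HA and the endothelial selectin Selp under the others. Hpgd, Egfl6 and Mme also separate the wild-type culture sets. Endothelial markers were lower in 12, 12, 12, 13 and 13 of 13 cases (12, 12, 13, 13 and 13 adjusted over the list alone). Under the 5 treatments camera gave adjusted p = 0.0327, 0.0362, 0.0103, 0.0417 and 0.0267 with an estimated correlation. Chondrocyte markers were higher in 6 of 14 cases under each treatment (6 adjusted over the list alone, 7 under TSG-6) and kept their call under LPS, TSG-6 and TSG-6 with HA (adjusted p = 0.0357, 0.00721 and 0.0292 with an estimated correlation). Cell cycle genes were lower in 26 of 28 cases under TNFa (27 adjusted over the list alone; adjusted p = 0.0375 with an estimated correlation). There, 5 of 15 prostaglandin and nitric oxide genes were higher and 1 lower (6 adjusted over the list alone; adjusted p = 0.0327 with an estimated correlation).

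The genes that differed between genotypes numbered 4273 under TNFa (2476 higher, 1797 lower in knockout-labelled cultures; 4158 with the culture set as a random block) and 4363 under LPS (2440 higher, 1923 lower; 4258 with the block). They numbered 3444 under TSG-6 (1865 higher, 1579 lower; 3551 with the block), 4236 under HA (2404 higher, 1832 lower; 4133 with the block) and 3935 under TSG-6 with HA (2186 higher, 1749 lower; 3799 with the block). Without WT LPS replicate 2 the LPS count was 2560, without WT TSG6 replicate 2 the TSG-6 count was 2052, without WT HA replicate 2 the HA count was 2567 and without WT TSG6HA replicate 2 the count for the combination was 2081. Without the arrays with a high 18S signal the counts under LPS, HA and the combination were 2262, 2630 and 1614.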

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

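For the endothelial markers and for the HA and TSG-6 preparations all tests were chosen only after the results had been seen. For the LPS response the comparison over all 27 genes and the count of 22 were written before, and the other tests were added after.

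Endothelial markers were lower in untreated knockout-labelled than in wild-type cultures, by a median of -4.67. Endothelial cells mixed into the wild-type cultures may be the source. That 12 of the 13 markers were at least 2-fold lower restates the pattern and does not test this, so it stays open. A smaller share of fibroblasts in the wild-type cultures would raise the markers of every other cell type that is present. The medians of the macrophage (0.091), lymphocyte (0.045), adipocyte (0.019) and skeletal muscle markers (0.013) lay near 0. Centred values do not show whether these cells were in the cultures, so this stays open too. Linkage to Tnfaip6 stays open. Of its 47 neighbours 40.4% changed against 37.5% of the other genes (Fisher's exact test, one-sided p = 0.394), but a linked gene acting on genes elsewhere would leave this share as it is. A difference between cultures rather than genotypes cannot be told apart from the genotype, because each genotype holds about 2 culture sets, which differ in the endothelial score by 1.029 within the knockout-labelled and by 0.319 within the wild-type arrays, against 3.773 between genotypes. The markers Cdh5 and Emcn helped to define the knockout-labelled sets, and without them the differences were 0.599, 0.356 and 3.351. An effect of the genotype on endothelial genes in fibroblasts stays open and was not tested.

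In knockout-labelled cultures the genes that changed under HA moved as they did under LPS. With genes called on 1 part of the untreated arrays and directions read on the other, 98.7% moved the same way (mean over 70 splits, median 54.5 genes, lowest 82.2%). The first form, with all untreated arrays in both comparisons, gave 100% and was replaced because shared arrays favour it. Treated arrays of the same number also deviate together, so the test was repeated with HA and LPS arrays of different numbers (100 draws, 50% expected with nothing shared). Of the genes pooled over all draws 68.1% moved the same way. The mean over draws, as used for the splits, was 96.2% (97 draws with at least 5 genes, lowest 48.6%). It and the subsets of draws below were taken only after the pooled share had been seen. The difference came from 5 draws that set arrays with a high 18S signal against each other (2396 of 4005 genes, 48.9%), and in the 61 draws that split the high untreated arrays evenly the pooled share was 98.8%. A trace of bacterial product in the HA preparation and HA acting on the same pathway both predict this, so the tests do not separate them. In wild-type cultures LPS shared 17 higher and 7 lower of the 24 HA genes. It shared 41 and 16 of the 78 TSG-6 genes, with 0 opposite for either. Those counts share untreated arrays and the tests above were not run there, so a trace stays open there too. For TSG-6 in knockout-labelled cultures, such a trace as the whole cause is argued against by TSG-6 with HA against HA alone. There the interferon-stimulated genes had a median of -0.779 (quartiles -1.036 and -0.518). Against untreated cultures the list lost its call under TSG-6 and TSG-6 with HA. Untreated array means (-0.797 to 0.129) overlapped those of TSG-6 (-0.811 to -0.705) and TSG-6 with HA (-1.016 to -0.571), so that contrast decides nothing. The 5' minus 3' values of Actb also differ between TSG-6 with HA and HA. Their trend with the list's mean within groups of knockout-labelled cultures would give a shift of -0.077 ± 0.063 (-0.121 ± 0.125 without KO untreated replicate 4).

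Among genes whose LPS response was smaller in knockout-labelled cultures (27), a higher untreated level with the same level reached under LPS could account for part. Over all 27 the median difference between genotypes was 0.822 when untreated and -0.162 under LPS, but the genes went both ways, so this median decides nothing. A higher untreated level as the cause for all 27 is argued against by 6 that were lower when untreated, past the threshold (Csf2, Csf3, Pf4, Lcp2, Fbp1 and Acot1). For the 16 that were higher when untreated, past the threshold, the median under LPS was 0.343 (-0.409 to 1.439), with 7 still over 0.5 above wild-type, so the same level was not reached by all of them and the explanation stays open for the others. Endothelial cells in the wild-type cultures as the source of the larger response predict that the same genes also respond less to TNFa, and 22 of the 27 did, 7 of them past the threshold. The other 5 include Csf3, whose TNFa response was larger in knockout-labelled cultures (1.835 ± 0.467, adjusted p = 0.0488), and Csf2 (0.754 ± 0.318, adjusted p = 0.539). Because both comparisons share the untreated arrays, the test was repeated on separate parts of them, where 75.4% did (20 splits, median 21 genes), only just over the 75% asked of it. With LPS and TNFa arrays of different numbers the share was 81.1% (100 draws, median 13 genes, 50% expected with nothing shared). A higher untreated level that ends at the same treated level would make the TNFa response smaller too, however the untreated arrays are split. Cxcl3, for example, was 2.456 higher when untreated, with a TNFa interaction of -1.29. The 50% leaves this out, so the shares do not tell these explanations apart. Endothelial cells as the source stay open, as does an effect of the genotype itself, which was not tested.

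The response differed between genotypes, by a test of the difference, for 147 genes under TNFa, 39 under LPS, 15 under TSG-6, 8 under HA and 33 under TSG-6 with HA. Here too the genotype and the cultures cannot be told apart. Without WT TNFa replicate 2 and WT LPS replicate 2 the first 2 counts were 43 and 23. Under TNFa these were led by Nos2 (2.467), Sntb1 (2.329), Cited1 (2.277), Plagl1 (-2.694), Mmp10 (-2.287) and Hsd11b2 (-2.262). The TNFa response also differed for the lists of MHC class I genes (0.498), prostaglandin and nitric oxide genes (0.09) and hyaluronan genes (0.179). Camera gave adjusted p = 0.0443, 0.0463 and 0.0443 with an estimated correlation. Among prostaglandin and nitric oxide genes Nos2 alone passed the threshold by limma, and no hyaluronan gene did. Under LPS the leading genes were Cldn5 (2.273), Fabp4 (2.036), Nmb (1.565), Csf2 (-3.194), Cxcl2 (-2.997) and Csf3 (-2.755), and the lists were NF-kB genes (-0.336) and chemokines (-0.21). For TSG-6 they were Col8a2 (1.475), Sstr2 (1.13), Nectin2 (0.93), Fbp1 (-1.721), Csf2 (-1.674) and Sema7a (-1.339). For HA they were Sprr1a (1.095), Sstr2 (0.986), Gprc5b (0.78), Csf2 (-2.29), Lcp2 (-1.462) and Pf4 (-1.39). For TSG-6 with HA they were Cldn5 (1.511), Tm6sf1 (1.344), Sstr2 (1.23), Csf3 (-2.647), Csf2 (-2.462) and Plin4 (-2.086), with the NF-kB list at -0.409. Without single arrays the TSG-6 count went as low as 1 (WT TSG6 replicate 1), the HA count as low as 2 (WT HA replicate 1 or 2), and the count for the combination was 59 (WT TSG6HA replicate 1) or 20 (WT TSG6HA replicate 2 or KO TSG6HA replicate 3).

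Among 60 groups of values tested for an array far from the rest of its group, of which chance picks out about 1 in 20, 6 stood apart. The control probe sets of Actb and Gapdh were added to these after the other values had been seen. The 18S ribosomal RNA signal was 1.774 on WT untreated replicate 5 (nearest -0.139, n = 5) and 4.126 on KO HA replicate 4 (nearest -0.245, n = 4). The mean of synovial fibroblast markers was -0.124 on KO HA replicate 2 (nearest 0.06, n = 4). The 5' minus 3' value of Actb was -0.163 on WT untreated replicate 1 (nearest 0.06, n = 5), -0.735 on KO untreated replicate 4 (nearest -0.259, n = 8) and -0.285 on KO TNFa replicate 3 (nearest -0.023, n = 4). Without KO untreated replicate 4 the counts under TSG-6 and TSG-6 with HA in knockout-labelled cultures were 800 and 1547.

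Other groupings of the same arrays into groups of the same sizes were counted for each comparison with at least 3 arrays per group. For the combination against a single treatment all 35 were counted. Elsewhere 100 were, the real one included, out of 165 (TSG-6), 495 (the other treatments) or 1287 (untreated genotypes). For TNFa (2552 genes, highest other 1577), TSG-6 (864, 759) and TSG-6 with HA (1809, 607) in knockout-labelled cultures, only the real grouping of 100 had as many. The same held for the combination against HA among 35 (325, 2). A chance division of the arrays is argued against here, if they are taken as independent. For the untreated genotypes 1 of 100 groupings had as many (6832; 4703), but this treats the arrays as independent, and with about 2 culture sets per genotype it does not exclude a chance difference between cultures. For LPS (326, 2 of 100, highest other 461) and HA (117, 2 of 100, 292) 1 other grouping gave more genes than the real one, so these counts do not exclude chance. That grouping had 3 of its 4 arrays in culture set a for LPS and all 4 for HA, and 1 grouping does not show whether the culture sets are the reason. With the culture set as a block the counts were 720 and 305. The combination against TSG-6 gave 0 genes by limma (612 at an unadjusted p under 0.05), so all 35 groupings had as many (highest other 14) and their count says nothing about chance.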

How the results depend on the processing

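The culture-set block, leaving out the arrays with a high 18S signal and centring each array on its median were chosen only after the results had been seen, and the cause was not tested for any change below except where the smaller number of arrays, or of residual degrees of freedom in a fit over fewer groups, sets it. The alternative without a filter on dim probe sets was not run, since no filter could be applied to centred values. Of 833 pairs of named gene and comparison, the culture-set block kept 833 in direction and on the same side of the threshold, centring all but 4, the replicate block 805, the mean of probe sets 797, a fit over only the groups compared 695 and leaving out the high 18S arrays 663. Cyclic loess kept 499 and lost 38, with the comparisons between genotypes left out after its result there had been seen. Of 246 list calls, centring kept 243, the mean of probe sets 235, the fit over fewer groups 232, leaving out the high 18S arrays 204 and the estimated correlation 63. Where it was run, the culture-set block kept 176 and lost 7. Cyclic loess kept 165 and lost 18, again with the comparisons between genotypes left out. The replicate block kept 197, lost 39 and reversed 10. Leaving out a replicate of a group of 2 leaves 1 array, which is assumed to vary like the other groups. Signal over background was not used here, so dim genes could not be told from bright ones.

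Cyclic loess was run on all 25 comparisons and then left out for the 6 between genotypes after its result had been seen. On centred values its axis, the mean of an array and the others, follows the genotype (r = -0.748 to -0.798, at most 0.139 in size for the other comparisons), and it turned Serpinb6b in untreated cultures from -7.65 to 0.515. It gave 5431 genes for the untreated genotypes (6832 without it), 1920 under TNFa (4273), 1865 under LPS (4363), 831 under TSG-6 (3444), 1500 under HA (4236) and 1231 under TSG-6 with HA (3935). In the comparisons where it was kept, it gave 9 genes for the difference between genotypes under TSG-6, 4 under HA, 56 under TSG-6 with HA and 4 for the combination against HA in wild-type cultures, and mean Tnfaip6 values of 0.291 (WT LPS) and -0.042 (WT TSG6).

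A fit over only the groups compared gave 289 genes for TNFa, 34 for TSG-6, 11 for HA and 49 for TSG-6 with HA in wild-type cultures. It gave 560 for TSG-6 and 60 for HA in knockout-labelled cultures, 2794 between genotypes under HA, 4, 4 and 13 for the difference between genotypes under TSG-6, HA and the combination, and 0 (wild-type, limma, against 580 at an unadjusted p under 0.05 in the full fit) and 51 (knockout-labelled) for the combination against HA.

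With the replicate number as a block the counts were 823 (TNFa), 478 (LPS), 299 (TSG-6), 49 (HA) and 487 (TSG-6 with HA) in wild-type cultures. They were 762 (LPS) and 361 (HA) in knockout-labelled cultures, 227, 76, 30 and 89 for the difference between genotypes under TNFa, LPS, TSG-6 and the combination, and 8 (wild-type) and 760 (knockout-labelled) for the combination against HA. The numbers pair the treated wild-type arrays, where all 20 pairs of the same number correlated above 0.1 (median 0.565, lowest 0.405), but not the untreated ones with them (5 of 10 pairs, median -0.171). In knockout-labelled cultures 27 of 36 treated pairs did (median 0.468) and 7 of 19 with an untreated array (median 0.044), and 13 of 42 arrays correlated best with one of their own number. This block reversed the medians of complement genes under HA (-0.132) and the combination (-0.031) in wild-type cultures. It also reversed those of cell cycle genes under TSG-6 in knockout-labelled cultures (-0.143) and in the differences between genotypes under LPS (-0.122) and HA (-0.205), of chemokines in that under TSG-6 (0.032), of cholesterol genes in those under HA (-0.324) and the combination (-0.086) and of endoplasmic reticulum stress genes in those under HA (-0.044) and the combination (-0.082).

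With the culture set as a block the counts were 835, 523, 214, 68 and 448 in wild-type cultures for TNFa, LPS, TSG-6, HA and the combination. They were 720, 1539 and 305 in knockout-labelled cultures for LPS, TSG-6 and HA, 404, 103, 87, 18 and 211 for the differences between genotypes, and 19 (wild-type) and 820 (knockout-labelled) for the combination against HA.

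Without the arrays with a high 18S signal the counts were 230 (TNFa), 118 (LPS) and 51 (TSG-6 with HA) in wild-type cultures. They were 134 (LPS), 435 (TSG-6), 63 (HA) and 1080 (TSG-6 with HA) in knockout-labelled cultures, 2262, 2630 and 1614 between genotypes under LPS, HA and the combination, 32, 20, 4, 1 and 7 for the differences between genotypes and 0 for the combination against HA in wild-type cultures. The correlations were 0.713 between TSG-6 and the combination (knockout-labelled) and 0.467 between genotypes under TNFa. The mean of probe sets gave 3 genes for the combination against HA in wild-type cultures. The estimated correlation left 63 list calls.

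With the untreated arrays split, correlations fell to 0.382 (TSG-6 with the combination) and 0.342 (TSG-6 with LPS) in wild-type cultures and to 0.514 (TNFa with LPS), 0.646 (TSG-6 with the combination), 0.349 (HA with the combination), 0.345 (TSG-6 with LPS) and 0.45 (HA with LPS) in knockout-labelled cultures.

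Leaving out 1 array gave 219 to 444 genes for TNFa, 93 to 206 for LPS, 20 to 75 for TSG-6, 18 to 29 for HA and 59 to 395 for the combination in wild-type cultures. In knockout-labelled cultures the ranges were 1884 to 2615, 200 to 328, 322 to 937, 61 to 122 and 1111 to 1872. Between genotypes they were 6340 to 6798 (untreated), 2898 to 4134, 2560 to 4184, 2052 to 3437, 2567 to 4033 and 2081 to 3794, and for the differences in response 43 to 163, 23 to 42, 1 to 17, 2 to 9 and 20 to 59. The combination gave 0 to 26 against TSG-6 and 0 to 23 against HA in wild-type cultures and 169 to 369 against HA in knockout-labelled ones, list calls ran from 237 to 258, and the correlation between genotypes under LPS from 0.382 to 0.544. The arrays that moved a count by over 1.5 times are named beside each count in the report. Some list medians reversed, and their lowest and highest values without 1 array were as follows. Complement genes ran from -0.125 (without WT TNFa replicate 1) to 0.945 under TNFa, from -0.203 (WT HA replicate 1) to 0.719 under HA and from -0.463 (WT TSG6HA replicate 1) to 0.849 under the combination in wild-type cultures. Cholesterol genes ran from -0.034 (WT TSG6 replicate 2) to 0.596 under TSG-6, from -0.078 (WT TSG6HA replicate 2) to 0.563 under the combination and from -0.158 (WT HA replicate 1) to 0.636 in the difference between genotypes under HA. Matrix proteases ran from -0.115 (WT TSG6HA replicate 1) to 0.281 under the combination. In the differences between genotypes, cell cycle genes ran from -0.079 (WT LPS replicate 1) to 0.613 under LPS and collagens from -0.09 (WT TSG6 replicate 2) to 0.211 under TSG-6.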

Other observations

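The tests here were fixed beforehand. Genes of oxidative stress and metal binding were called under LPS in both genotypes (adjusted p = 0.000751 in wild-type and 0.0371 in knockout-labelled cultures with an estimated correlation). In wild-type cultures 2 of 14 rose (4 adjusted over the list alone), the cystine transporter Slc7a11 (1.04 ± 0.21) and the metallothionein Mt2 (0.65 ± 0.14). In knockout-labelled cultures Mt1 (0.87 ± 0.18) and Mt2 (0.37 ± 0.10) rose and the glutathione transferase Gsta4 fell (-0.53 ± 0.12; 8 adjusted over the list alone). Under HA in knockout-labelled cultures 1 of 14 rose, the heme oxygenase Hmox1 (1.16 ± 0.24; 5 adjusted over the list alone), with adjusted p = 0.0201 with an estimated correlation.

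Of 15 prostaglandin and nitric oxide genes, 2 rose under LPS in each genotype (2 adjusted over the list alone in each), Nos2 and Ptges2. Nos2 rose by 1.66 ± 0.31 and Ptges2 by 0.56 ± 0.12 in wild-type cultures, with adjusted p = 0.0264 for the list with an estimated correlation. In knockout-labelled cultures the adjusted p was 0.00881 with an estimated correlation. Of 14 chondrocyte markers 1 fell under LPS in wild-type cultures, the fibril collagen Col11a1 (-1.0 ± 0.18; 2 adjusted over the list alone), with adjusted p = 0.0264 with an estimated correlation.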
